A study of Mus musculus with 4 samples.

How the data were processed

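RNA was prepared from 4 cultures of mouse bone marrow-derived macrophages, untreated or given LPS, the histone demethylase inhibitor GSK-J4, or both. Per the labels' protocols, cells were grown in GM-CSF for 7 days, the inhibitor was present over 2 days and the LPS exposure lasted 1 hour. RNA was taken up in Trizol, and libraries were made with an Illumina TruSeq RNA kit. Dose and strand setting are not given in the sources used here. Groups were taken from the treatment label of each sample, and each group held 1 library. Bowtie 0.12.2 and the mouse build mm9 are named per the submitters' processing notes, and the read counter is not given in the sources used here. The reference tables at hand describe another build, so no coordinates are printed.

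The authors deposited 3 tables, each comparing the untreated library with another by DESeq, per the file headers. Each table holds a normalized signal per gene and library, being reads divided by a size factor made within that table by the authors. Each also holds the authors' p-value and adjusted p-value per gene, quoted here only as theirs. The authors' fold and log2 columns were not used, because the values were recomputed. The normalized values were whole multiples of the value of 1 read. Whole numbers within 0.001 reads came out for 100% of values in each of the 3. The untreated reads recovered from the tables were identical for all genes, and genes missing from a table had 0 untreated reads elsewhere, so they were read as 0. The tables name 15674 genes, 14311 of them in every table. Symbols came from the tables for 15606 identifiers and from a reference name table for 56, and 12 stayed without one.

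Recovered reads were 14847703 for untreated, 15061580 for LPS, 16709440 for GSK-J4 and 16463536 for GSK-J4 with LPS. They were put on 1 scale with median-of-ratios size factors over the 4 libraries, 1.17, 0.743, 1.29 and 0.922 in the same order. A fold change is log2 of the ratio of normalized reads after adding 1 to each, which understates the change of low genes. Genes needed a mean of at least 20 normalized reads over the 4 libraries, which 11005 met. Counts give genes at least 2-fold higher or lower. With 1 library per group these fold changes and counts carry no test. Counting intervals are exact conditional binomial (Clopper-Pearson) 95% intervals of the ratio of reads, without the added 1. They cover counting error only, because each group held 1 library. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error. A fold against a library at 0 reads was set against a floor of 3 reads in that library, and no fold is given where both libraries are at or under it.

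Gene lists and cell type markers were fixed before the data were examined, 30 lists of pathways and 8 of cell types. For each list and comparison the median log2 fold change of the measured members is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. This describes these libraries and is not a test of the conditions. Lists with fewer than 5 measured members have counts or medians only. Some list members are not listed in the tables and were not analysed here. For the developmental transcription factors, part of the result is withheld and left out. The named genes follow a rule fixed at the same time. It takes the 10 highest and 10 lowest per comparison with a mean of at least 50 normalized reads over the compared libraries, leaving out predicted genes, clone names, small RNAs and pseudogenes. It also takes up to 4 members with the largest fold change of each list described, 10 genes always named (Kdm6a, Kdm6b, Ezh2, Tnf, Il6, Il1b, Il12b, Il10, Ccl2 and Csf2), and the 10 widest drops and gains of the response. LPS-responsive genes for the difference of responses had a mean log2 response of at least 1, or at most -1, over both responses. S100a8 in the comparison of the LPS libraries falls outside this rule and was chosen after its values were seen.

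Reads of near-identical genes cannot be separated here with certainty. This touches Ifit1bl1 and Ifit3, Ms4a4c and Ms4a6b, Apol7c, Ear1, Ccl2 and the Bcl2a1 genes. Overlapping and antisense genes are likewise uncertain, as the counting strand is not given in the sources used here.

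The counting rule was tested on simulated Poisson libraries made from the real means and library sizes, with 200 genes changed by known folds. For LPS against untreated, 100% of 50 genes changed 4-fold, 52.0% of 50 changed 2-fold and 10 of 10809 unchanged genes came out at least 2-fold apart. For GSK-J4 against untreated, 26 of 10816 unchanged genes did. Of 100 random lists of 20 genes, 8 fell outside the central 95%, against 100 of 100 moved by 2 on the log2 scale. Alternatives tried were scaling by library total, upper quartile and edgeR's TMM, the authors' own normalized values, other pseudocounts, minimums and fold sizes, the counting interval, and an edgeR quasi-likelihood fit with additive LPS and GSK-J4 terms. That fit has 1 residual degree of freedom, the difference between the LPS responses. In libraries simulated with a dispersion of 0.05 it called 12 of 50 genes changed 2-fold by LPS, 50 of 50 changed 4-fold and 6 of 10805 unchanged genes. No GSK-J4 effect and no difference between the LPS responses was simulated. These figures therefore do not say how many real changes the fit would find, least of all for its GSK-J4 term. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.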

Results

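Messenger RNA was measured by RNA sequencing in macrophages grown from the bone marrow of C57BL/6 mice in GM-CSF, a growth factor that drives myeloid cells, for 7 days. The 4 libraries made up 4 groups of 1 library each. These were untreated cells, cells given LPS for 1 hour, cells given GSK-J4 for 2 days, and cells given both. LPS is a bacterial cell wall component sensed by Toll-like receptor 4. GSK-J4 is a cell-permeable inhibitor of KDM6A and KDM6B, the demethylases that remove methyl groups from lysine 27 of histone H3. The question set by the series title is whether this histone mark governs cytokine transcription in macrophages. The deposited tables held 14847703 reads for the untreated library, 15061580 for LPS, 16709440 for GSK-J4 and 16463536 for GSK-J4 with LPS. With 1 library per group there is no replicate check of any difference below, and each interval covers counting error only. The fold changes carry no test, and an additive fit over the 4 libraries is given beside the counts it covers. The LPS exposure of 1 hour is taken from the labels and was not settled from the data.

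The libraries parted mainly by LPS. Across the 11005 genes with a mean of at least 20 normalized reads, Pearson's r of the log2 values was 0.991 between untreated and GSK-J4. It was 0.922 between LPS and GSK-J4 with LPS, and 0.795 between untreated and LPS. These correlations are across genes, which are not independent replicates. Scaling to the library total instead of the median ratio moved the median log2 fold change of all genes by -0.68 for LPS against untreated. The same change moved it by -0.49 for GSK-J4 with LPS against untreated, by -0.46 for GSK-J4 with LPS against GSK-J4 and by 0.18 for GSK-J4 with LPS against LPS. Upper-quartile scaling moved the first of these by -0.19, the second by -0.11 and the third by -0.13, so the fold changes below are relative to the median gene.

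LPS alone was compared with no treatment to measure the inflammatory response itself. Il6 and Il12b had the largest fold changes by the naming rule. Tnf (ENSMUSG00000024401), the main early inflammatory cytokine, stood at 312 normalized reads without and 66912 with LPS, a log2 fold change of 7.74 with a 95% counting interval of 7.60 to 7.90. Il6 (ENSMUSG00000025746) was higher by 12.53 (interval 11.78 to 13.84, from 9 reads to 38140). Il12b, a subunit of interleukin 12 and interleukin 23, was higher by 12.23 (11.54 to 13.38) and Il1b by 9.13 (8.97 to 9.30). Ccl2, which attracts monocytes, was higher by 4.70 (4.61 to 4.80). Il10, an anti-inflammatory cytokine, had 3 reads without and 88 with LPS, a log2 fold change of 5.07 (3.94 to 7.84). Csf2, which encodes GM-CSF, had 0 reads without LPS and 21 with it, which makes it at least 11.1-fold higher against a floor of 3 reads.

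At least 2-fold differences between these libraries covered 1744 genes that were higher and 1530 that were lower with LPS. Library-total scaling gave 997 higher and 3811 lower, upper-quartile scaling 1490 and 2024. The additive edgeR fit, which takes the LPS response as equal with and without GSK-J4, called 769 genes higher and 375 lower. All 17 measured inflammatory cytokines were at least 2-fold higher, with a median log2 fold change of 7.51, or 6.64 with the 2 members at 0 reads set to the floor. So were 16 of 18 chemokines (median 5.22), with Cxcl10 at 10.80 and Cxcl1 at 8.90. All 25 genes of the NF-kB pathway and its feedback were higher (median 2.90), among them Ptgs2, the inducible cyclooxygenase, at 10.96 and the inhibitor Tnfaip3 at 5.32. All 24 type I interferon response genes were higher (median 6.07, or 6.03 with the member at 0 reads set to the floor), including Ifit1 at 9.96 and the antiviral enzyme Rsad2 at 9.96. The 20 genes of the secondary LPS response, which need newly made factors, were all higher with a median of 4.58, and Nos2, the inducible nitric oxide synthase, reached 10.38. Each of these 5 medians lay at percentile 100 of 10000 random lists matched on expression. MAPK phosphatases and feedback genes also lay there, with 14 of 18 higher and a median of 1.83. Some of these lists share members, so their medians are not independent. Il6 and Il12b are in the cytokine and secondary LPS lists, and Tnfaip3 is in the NF-kB and MAPK feedback lists. Among cell type markers, those of dendritic cells had a median of 1.09 (percentile 99.8, 6 of 11 higher and 2 lower). Stromal and endothelial markers had 1.01 (percentile 98.6, 3 of 6 higher), which lay inside the central 95% with a minimum of 5.

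Immediate-early genes went both ways. Of 15 measured, 7 were at least 2-fold higher and 4 lower, with a median of 0.94 at percentile 99.7. Junb was higher by 2.42, while Fos, a classical first responder to stimulation, was lower by a log2 fold change of -3.19 (-3.75 to -2.73). Toll-like receptor signalling genes had a median of 0.75 (percentile 99.6, 10 of 25 higher), with the LPS co-receptor Cd14 at 2.68 and Tlr2 at 2.52. Inflammasome genes had a median of 0.76 (percentile 98.035, 6 of 13 higher and 2 lower), with Nlrp3 at 3.66 and the lowest member at -2.76.

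The list medians of sterol and lipid metabolism lay below those of random lists, although most members were less than 2-fold apart. Cholesterol biosynthesis genes had a median of -0.49 (percentile 0.01, 7 of 23 at least 2-fold lower), with the synthesis enzymes Dhcr7 at -1.81 and Lss at -1.52. Lipid handling genes under the receptor LXR had a median of -0.23 at percentile 0.01, with 5 of 21 at least 2-fold lower, 0 higher and 8 above 0, and with the desaturase Scd2 at -2.45. Alternative activation genes, linked to tissue repair, had a median of -0.47 (percentile 0.15), with 7 of 18 lower and 2 higher, among them the arginase Arg1 at -2.25 and the chemokine Ccl17 at 2.21. The 10 lowest single genes included Cd300lb at -5.62, the cannabinoid receptor Cnr2 at -5.58 and the lipid phosphatase Lpin1 at -5.56. Ankrd63 had 159 reads without LPS and 0 with it, at least 33.6-fold lower.

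**Figure D1:**
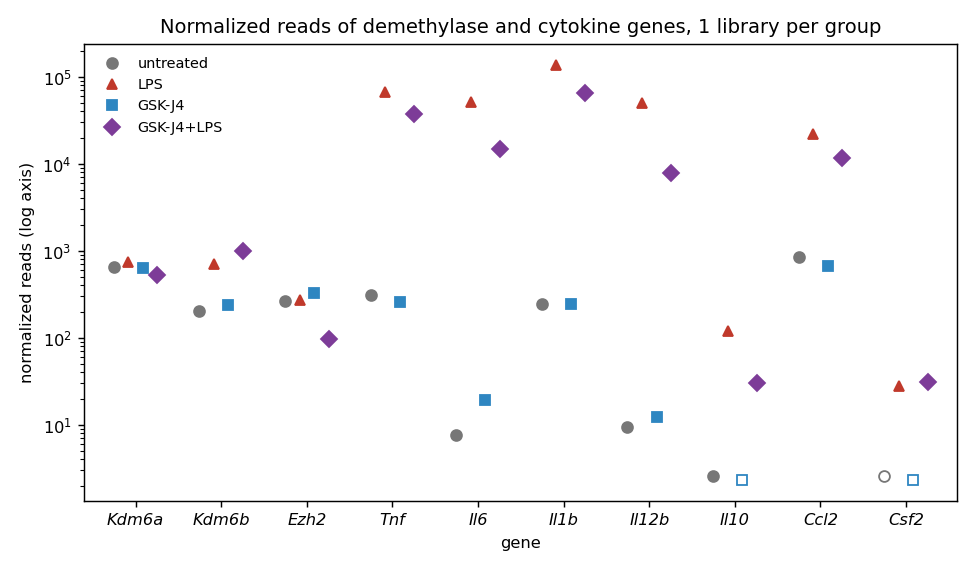
Normalized reads (log axis) of 10 genes in the 4 libraries, 1 point per library, with an open symbol at the level of 3 reads where a library had 0 reads. Tnf lay at 66912 in the LPS library and at 37156 with GSK-J4 and LPS, while Il12b lay at 49949 and 7799.

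GSK-J4 without LPS was compared with no treatment to measure the effect of the inhibitor on resting cells. Of the 11005 genes, 64 were at least 2-fold higher and 65 lower, or 53 and 56 with libraries at 0 reads set to the floor. A minimum mean of 100 reads gave 23 higher and 8 lower, a minimum of 5 gave 410 genes in all and a pseudocount of 5 gave 53. The counting interval left out equal levels for 44 of the higher and 48 of the lower genes. The additive edgeR fit called 0 genes for GSK-J4, with 93 of 11005 at an unadjusted p under 0.05. That is a smaller share than the 0.05 that unchanged genes would give. The fit counts the difference between the LPS responses as noise, so its 0 calls do not show that GSK-J4 had no effect. In simulated libraries 26 of 10816 unchanged genes came out at least 2-fold apart from counting error. Cd5l, a macrophage survival factor, was the highest by the naming rule at 3.90 (3.02 to 5.45), from 7 reads to 133. Interferon-induced genes followed, with Ifit1bl1 at 1.98 (1.46 to 2.61) and Ifit3 from 45 reads to 143 (log2 interval 1.04 to 2.04). Both have close relatives in the genome that could share their reads. The type I interferon list had a median of 0.29 (percentile 100), or 0.25 with the member at 0 reads set to the floor, and 2 of its 24 members were at least 2-fold higher with that floor. Cebpb, a transcription factor of myeloid and inflammatory genes, was lower at -1.16 (-1.27 to -1.05), as were Pknox2 at -1.44 and Gdpd5 at -1.21.

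Of the 17 inflammatory cytokines, 1 was at least 2-fold higher and 0 lower with the inhibitor in resting cells, with libraries at 0 reads set to the floor. Their median was 0.00 (percentile 38.8), with 4 members at 0 reads in a library. Tnf was at -0.27 (-0.49 to -0.05), Il1b at 0.00 (-0.24 to 0.23) and Ccl2 at -0.32 (-0.45 to -0.19). Il6 stood at 9 reads without and 25 with GSK-J4, a log2 fold change of 1.23 (0.19 to 2.62). For the inhibitor's target genes no difference was detectable at this depth, with Kdm6a at -0.06 (-0.20 to 0.09) and Kdm6b at 0.23 (-0.01 to 0.48). Several lists had small medians above those of random lists, with no member at least 2-fold apart. These were 0.18 for ribosomal protein genes (percentile 100), 0.16 for MHC class II (99.6), 0.14 for housekeeping genes (99.4), 0.13 for DNA replication (99.7), chaperones (99.7) and LXR targets (99.6), 0.12 for cholesterol biosynthesis (99.9) and 0.11 for cell division (99.4). H3K27 methylation writers and erasers had 0.14 (99.5) and respiratory chain subunits 0.08 (97.85), but with a minimum of 100 the first turned to -0.0519 and both lay inside the central 95%. MAPK phosphatases and feedback genes had a median of -0.18 (percentile 0.15) and secondary LPS genes -0.13 (percentile 0.16), or -0.11 with the member at 0 reads set to the floor.

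The LPS libraries with and without GSK-J4 were compared to ask how the inhibitor alters stimulated cells. Several cytokine transcripts were lower in the library with the inhibitor. Il12b was lower by a log2 fold change of -2.68 (-2.72 to -2.64), Il10 at -1.93 (-2.63 to -1.34) and Il6 at -1.81 (-1.83 to -1.78). Il1b stood at -1.08 (-1.10 to -1.07), Ccl2 at -0.89 (-0.93 to -0.86) and Tnf at -0.85 (-0.87 to -0.83). For Csf2, with 21 and 29 reads, no difference was detectable at this depth (0.15, interval -0.71 to 1.04). Of the inflammatory cytokines, 8 of 17 were at least 2-fold lower, 9 less than 2-fold apart and 3 above 0 (median -0.97, percentile 0.01). Of the chemokines, 9 of 18 were lower (median -0.96, percentile 0.01), among them Ccl22 at -4.34 and Ccl17 at -3.12, which attract T cells, and Cxcl9 at -3.74. NF-kB pathway genes had a median of -0.56 (percentile 0.36), with 4 of 25 lower. The type I interferon list had a median of -1.75 (percentile 0), with 20 of 24 members at least 2-fold lower, among them Isg20 at -3.41 and Ifit3 at -3.29. Secondary LPS genes had a median of -1.02 (percentile 0, 10 of 20 lower), with complement C3 at -2.07.

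Genes of proliferation and antigen presentation were also lower. Of 24 cell division genes 22 were at least 2-fold lower with GSK-J4 and LPS than with LPS (median -2.64, percentile 0), including the topoisomerase Top2a at -3.52 (-3.76 to -3.31) and the ubiquitin ligase component Ube2c at -3.62. DNA replication genes had a median of -1.09 (percentile 0, 14 of 24 lower), with the ribonucleotide reductase Rrm2 at -2.44. The cell cycle inhibitor Cdkn1c was higher at 4.51 (3.75 to 5.62). Genes of MHC class II antigen presentation and costimulation had a median of -2.40 (percentile 0, 13 of 16 lower), with H2-DMb2 at -4.61, H2-Eb1 at -3.24 and H2-Ab1 at -2.99. Beside these lists, dendritic cell markers had a median of -1.36 (percentile 0, 8 of 11 lower), with the migration receptor Ccr7 at -4.90 and Fscn1 at -4.47. Granulocyte markers had a median of -2.73 (percentile 0), or -2.15 with the member at 0 reads set to the floor. The granulocyte proteins parted, S100a9 being lower at -6.44 (274 reads to 3, interval -9.11 to -5.26) and S100a8 higher at 1.64 (114 reads to 444, interval 1.35 to 1.96). Macrophage markers had a median of -0.78 (percentile 0.23, 6 of 14 lower), with the Fc receptor Fcgr1 at -3.45 and the complement component C1qb at -2.04.

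Some lists had medians above those of random lists with the inhibitor in LPS-treated cells, although most of their members were less than 2-fold apart. NRF2 antioxidant genes had a median of 0.83 (percentile 100, 6 of 17 at least 2-fold higher), with Srxn1 at 1.97 and heme oxygenase Hmox1 at 1.46. Immediate-early genes had a median of 0.42 (percentile 99.7), with 3 of 15 at least 2-fold higher and 5 below 0, and with Egr1 at 4.55 (3.99 to 5.28), Fos at 1.22 and Jun at 1.01. The lysosomal list had a median of 0.24 (percentile 99.95), with 2 of 24 at least 2-fold higher and 9 below 0, and with Ctsl at 1.38. Ctsk, the collagen-degrading cathepsin of osteoclasts, was at 2.59 (2.46 to 2.72), and the eosinophil ribonuclease Ear1, which has near-identical copies, at 5.12. Cyp26b1, a retinoic acid-degrading enzyme, was at 4.26. In total 792 genes were at least 2-fold higher and 1327 lower, while library-total scaling gave 1115 higher and 1065 lower. The additive edgeR fit, whose GSK-J4 term is shared with resting cells, called 0 genes, with 93 of 11005 at an unadjusted p under 0.05. This too is fewer than unchanged genes would give, so the 0 calls do not show that there was no effect. Ribosomal protein genes had a median of -0.70 (percentile 0.02, 5 of 29 lower). Toll-like receptor signalling genes had a median of -0.37 (percentile 1.945), with 6 of 25 at least 2-fold lower and 11 above 0. The lowest included Tlr9 at -3.61 and Irf8 at -2.50, and with a minimum of 100 the median lay inside the central 95%. Alternative activation genes had a median of -0.65 (percentile 0.23, 7 of 18 lower and 2 higher), with Mgl2 at -2.81, and with a minimum of 5 or 100 it lay inside the central 95%. The GSK-J4 comparisons without and with LPS share no library, and their log2 fold changes correlated across genes at r = -0.0199. Of the 65 genes at least 2-fold lower with GSK-J4 alone 31 were also lower here, against 7.84 for independent lists, and of the 64 higher genes 11 were also higher, against 4.61. Another 46 genes were at least 2-fold apart in opposite directions, against 12.4.

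**Figure D2:**
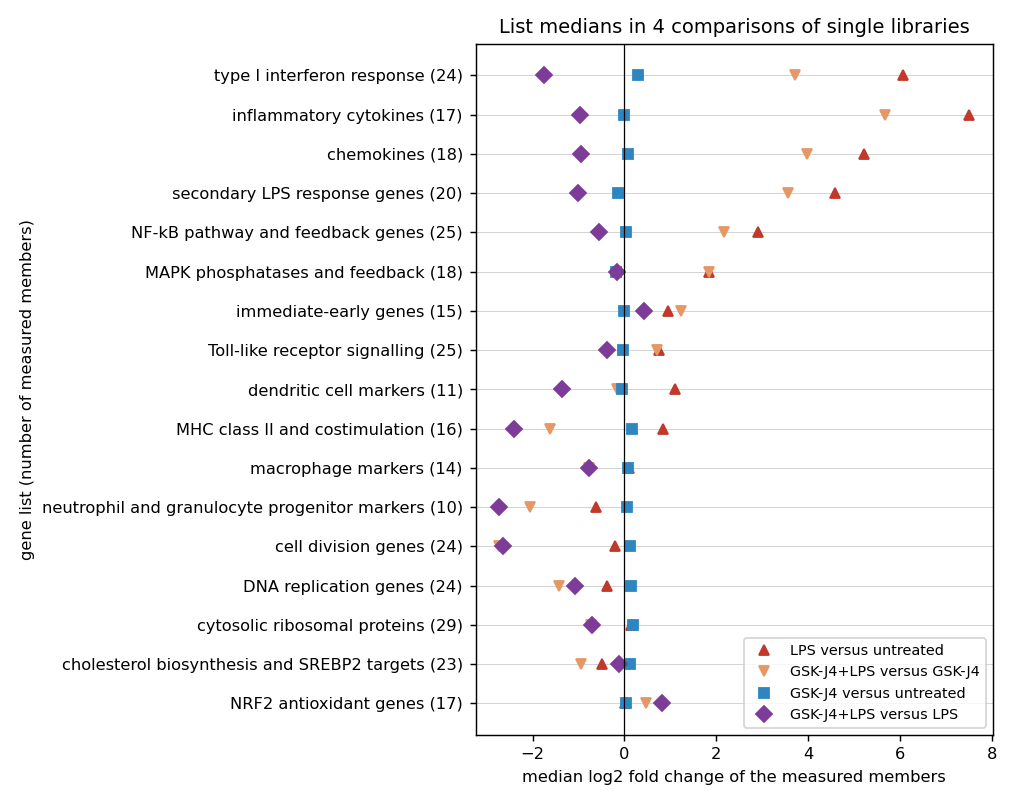
Median log2 fold change (horizontal axis) of the measured members of 17 gene lists (vertical axis, number of members in brackets) in 4 comparisons, 1 symbol per comparison. With library-total scaling every symbol of LPS against untreated would move by about -0.68. Cell division genes lay at -2.64 for GSK-J4 with LPS against LPS and at 0.11 for GSK-J4 against untreated.

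The LPS response in inhibitor-treated cells was measured between the GSK-J4 library with LPS and the one without. It covered 1435 genes at least 2-fold higher and 1453 lower, or 885 and 2674 with library-total scaling, and 769 and 375 for the LPS term of the additive edgeR fit. Against untreated cells the GSK-J4 library with LPS had 1416 genes higher and 1513 lower, or 843 and 2877 with that scaling. All 17 inflammatory cytokines were higher in the response with the inhibitor too (median 5.68, or 5.50 with the 3 members at 0 reads at the floor), with Il6 at 9.50 (9.01 to 10.20), Il12b at 9.19 (8.60 to 10.11), Il1b at 8.04 and Tnf at 7.16. The ligand Tnfsf15 led at 9.95 (9.63 to 10.35). The interferon list had a median of 3.71 and the chemokines 3.97, with 24 of 24 and 13 of 18 members at least 2-fold higher. Traf3ip3 had 514 reads in the GSK-J4 library and 0 after LPS, at least 122-fold lower. Cell division genes had a median of -2.73, with 22 of 24 lower and Cdc20 at -4.04, whereas LPS without the inhibitor gave a median of -0.21 (percentile 18.9) with 1 of 24 lower. Within the labelled 1 hour, a 4-fold fall needs a half-life of 30 minutes or less even if transcription stopped at once. Whether these falls came from LPS or from another difference between the GSK-J4 cultures was not tested. MHC class II and costimulation genes had a median of -1.62 with the inhibitor and 0.83 (percentile 97.2) without it. Cholesterol biosynthesis genes had a median of -0.94 in this response (percentile 0), with 11 of 23 at least 2-fold lower and 12 less than 2-fold apart.

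The LPS responses with and without GSK-J4 share no library. Of the 1744 genes higher with LPS alone, 1091 were at least 2-fold higher in the response with the inhibitor, where independent lists of these sizes would share 227. Of the 1530 lower genes 773 were shared, against 202. The log2 responses correlated across the 11005 genes, with Pearson's r of 0.754 and Spearman's rho of 0.674. For 1515 genes induced on average over both responses, the median difference, with minus without inhibitor, was -0.47, and 70.2% of these genes had the smaller log2 response with the inhibitor. Choosing the genes by the response with the inhibitor instead gave a median of -0.07 (53.1% smaller), and by the response without it -0.70 (81.1%). Of the induced genes, 454 had a difference of -1 or less and 118 a difference of 1 or more. The 1401 repressed genes had a median difference of 0.03, or 0.31 with library totals and 0.15 with upper quartiles. Choosing them by the response without or with the inhibitor gave 0.62 or -0.72. The widest drops by the naming rule were Ccl1 at -7.34, whose size rests on the added 1 because untreated cells had 0 reads, Ms4a4c at -6.93, Apol7c at -6.50 and Calhm6 at -6.41. The widest gains were Cyp26b1 at 5.53, Egr1 at 5.50 and Cdkn1c at 3.80. LPS alone did not raise these genes, with responses of -0.43, -1.58 and -0.50, against 5.10, 3.92 and 3.30 with GSK-J4. Among the lists, the interferon response had a median difference of -2.08 (percentile 0), MHC class II genes -2.72 (percentile 0), chemokines -1.06 (percentile 0), inflammatory cytokines -0.58 (percentile 1.08) and immediate-early genes 0.09 (percentile 82.7). Members at 0 reads in a resting library enter these medians through the added 1.

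**Figure D3:**
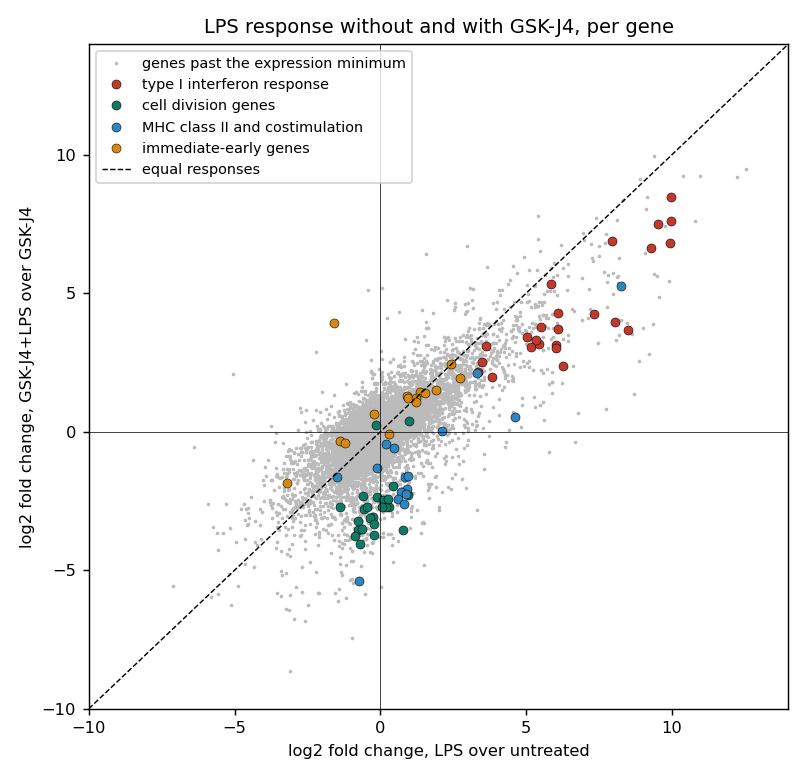
Log2 fold change of LPS over untreated (horizontal axis) against GSK-J4 with LPS over GSK-J4 (vertical axis), 1 grey point per gene for the 11005 genes, with members of 4 lists in colour and a dashed line at equal responses. The interferon genes lie to the right of 0, with medians of 6.07 and 3.71, and cell division genes have medians of -0.21 and -2.73.

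The histone methylation enzymes were themselves followed. Kdm6b was higher with LPS alone at 1.78 (1.56 to 2.01) and in the response with GSK-J4 at 2.07 (1.88 to 2.26). Kdm6a was at 0.17 (0.01 to 0.33) and -0.24 (-0.40 to -0.07) in the same comparisons. Ezh2, the methyltransferase that places the mark, was at 0.03 (-0.23 to 0.29) with LPS alone and at -1.75 (-2.11 to -1.43) in the response with GSK-J4. Of the 13 writers and erasers of H3K27 methylation, 4 were at least 2-fold higher and 1 lower with LPS (median 0.17), while 2 were lower and 0 higher for GSK-J4 with LPS against LPS (median -0.34, percentile 6.635). The 15 other JmjC demethylases had medians of -0.08 and -0.11 in these comparisons. With library-total scaling, Kdm6a, Ezh2 and the median of the writers and erasers lay below 0 for LPS against untreated, and the median of the other demethylases above 0 for GSK-J4 with LPS against LPS.

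Several lists gave a median within the central 95% of random lists for GSK-J4 with LPS against LPS. These were the ATF4 amino acid stress response (-0.04), endoplasmic reticulum chaperones (-0.10), heat shock genes (0.27), p53 targets (0.12), LXR targets (-0.06), cholesterol biosynthesis (-0.12), inflammasome genes (-0.30), MAPK feedback (-0.15), respiratory chain subunits (-0.09) and housekeeping genes (-0.19). With library-total scaling the medians of the ATF4, chaperone, LXR, cholesterol, MAPK feedback and respiratory chain lists lay above 0. Hypoxia-inducible genes had a median of 0.25 (percentile 98.5), which turned to -0.16 (percentile 36.0) with a minimum of 100 and lay inside the central 95% with a minimum of 5. Metallothioneins with zinc and iron handling genes had a median of 0.35 (percentile 99.7, 3 of 14 higher and 1 lower) and osteoclast and matrix-degrading genes 0.17 (percentile 97.7, 4 of 23 higher and 4 lower). Of the 40 developmental transcription factors listed, 4 passed the expression minimum, among them Lhx2 at -3.50 (-4.10 to -3.01), Meis1 at -1.31 (-2.06 to -0.65) and Hoxb4 at 0.41 (0.04 to 0.78).

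Few markers of lymphoid and erythroid cells passed the expression minimum. None of the B cell markers passed the expression minimum, and 2 of the T and NK cell markers did, Lck at -1.69 and Cd4 at 0.55 for GSK-J4 with LPS against LPS. The 3 erythroid and megakaryocyte markers had a median of -0.66 there, the 5 mast cell, basophil and eosinophil markers -0.17 (percentile 27.5, above 0 with library-total scaling) and the 6 stromal and endothelial markers -1.37 (percentile 0.73), with Kdr at -4.64.

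The authors' deposited tables called 98 genes higher and 1 lower for LPS against untreated at an adjusted p under 0.05. For GSK-J4 with LPS against untreated the authors' deposited table called 58 higher and 7 lower. For GSK-J4 against untreated, the authors' deposited table called 3 higher and 1 lower, namely Cd5l, Ftl1 and Mmp19 higher and Cebpb lower. These calls compare single libraries, not conditions. For GSK-J4 against untreated, Ftl1 was less than 2-fold apart by the fold changes used here. So were all measured members of the osteoclast and matrix-degrading list, which holds Mmp19. In the authors' deposited table for LPS, Il6 and Il12b had an adjusted p of 2.35e-06, Il1b 0.000169 and Tnf 0.00114, and Ccl2 at 0.123 and Il10 at 0.506 were not called.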

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

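All tests in this part were chosen after the results were seen. No difference between effects given here was tested, since each group has 1 library.

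The list median of MHC class II and costimulation genes for LPS was 0.83 without GSK-J4, inside the central 95% of random lists at percentile 97.2, and -1.62 with it, a difference of -2.45. Of its 16 members 4 were at least 2-fold higher and 1 lower without GSK-J4, and 2 higher and 10 lower with it. Dendritic cell markers moved beside them, with a median difference between the LPS responses of -1.46 (percentile 0). For 6 named genes the GSK-J4 difference was at least 2-fold in opposite directions without and with LPS, with both counting intervals on their own side of 0. Ifit1bl1 stood at 1.98 and -4.32, a difference of -6.30, Ms4a6b at 1.08 and -3.42, a difference of -4.50, and Ifit3 differed by -4.79. Il6 stood at 1.23 and -1.81, a difference of -3.03, with 9 and 25 reads behind the value without LPS. Cebpb (-1.16 and 1.09, a difference of 2.24) and Cyp26b1 (-1.27 and 4.26, a difference of 5.53) were lower without LPS and higher with it.

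GSK-J4 went with 129 genes at least 2-fold apart in resting cells and with 2119 in LPS-treated cells. Over library-total, upper-quartile and TMM scaling the lowest count in LPS-treated cells was 2098. Each scaling moves all genes by about the same amount, at most 0.18 here, so this count could hardly have fallen. It shows that the count did not rest on the choice among these scalings, and decides nothing further. Of 10 granulocyte markers 9 were lower, and they spanned 8.09 on the log2 scale, or 5.63 without S100a8. The second span ran from S100a9, with 274 reads and 3, to Mmp8, with 8351 and 5896. Whether other cells in the cultures also made these transcripts was not tested. The span therefore cannot decide about an even loss of granulocytes, and a loss of all or some of them stays open. Across genes the GSK-J4 differences without and with LPS correlated at -0.0199, which a library labelled GSK-J4 without effective inhibitor could also give. By direction 31 genes were lower in both, 11 higher in both and 46 opposite, where independent lists would give 7.84, 4.61 and 12.4. The excess lay in opposite as well as shared directions, so these counts do not decide whether that library held effective inhibitor. An action of the inhibitor that appears mainly on stimulation, or a difference between cultures, also stays open, untested.

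The interferon list had a median of 0.29 for GSK-J4 against untreated, or 0.25 with the member at 0 reads set to the floor, and 2 of its 24 members were at least 2-fold higher with that floor. At the carry-over rate of 0.0802% that 9 interferon genes would set, 15 cytokine and chemokine genes at least 100-fold higher with LPS should have gained 507 normalized reads, and they gained 54.3. The ratio was 0.107, with an interval of -0.11 to 0.32 from a normal approximation of counting error, not the exact one used elsewhere. Reads carried over from an LPS library, as the whole source of the gain, need 0.5 to 2, and the interval lay below this. However, the bound first set asked for an interval under 0.2, which left the test undecided. The bound of 0.5 was adopted after the value was seen. The ratio therefore speaks at most against carry-over as the whole source, and carry-over of a part stays open. An inhibitor effect or a difference between cultures stays open, untested.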

How the results depend on the processing

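No replicate could be left out and no paired analysis was possible because each group has 1 library, the authors' values cover only comparisons against untreated cells and not the difference between responses, and the edgeR fit has no term for the combined treatment. Scaling set without the GSK-J4 library, and a response with GSK-J4 taken against untreated cells, were chosen after seeing the data. The count for GSK-J4 against untreated moved under the most settings. Its 129 genes became 53 with pseudocount 5, 410 with a minimum of 5, 31 with a minimum of 100 and 1376 without one. Of the 129 genes, 92 also had a counting interval that left out equal levels. Pseudocount and minimum act on genes with few reads, and no further cause was tested.

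Without a minimum the counts were 5565 for LPS against untreated, 5266 for GSK-J4 with LPS against untreated, 4730 against LPS and 5172 against GSK-J4, and with a minimum of 100 the count against LPS was 1389. At 1.5-fold they were 5374, 4994, 4068 and 4932 in that order, and 478 for GSK-J4 against untreated. At 4-fold they were 1258, 1168, 581 and 1174, and 16 for GSK-J4. These follow from the thresholds. The additive edgeR fit called 1144 genes for LPS in either LPS comparison, 769 higher and 375 lower, with 3242 at an unadjusted p under 0.05. It called 0 for GSK-J4, alone or with LPS, with 93 of 11005 at an unadjusted p under 0.05, fewer than unchanged genes would give. It treats the difference between the LPS responses as noise, so the 0 calls do not show that GSK-J4 had no effect. Counts stayed within 1.5 times under each scaling and, but for GSK-J4 alone, each pseudocount, while the higher share of LPS against untreated went from 53.3% to 20.7% with library totals.

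The median difference of induced genes was -0.41 without a minimum, and -0.70 or -0.0677 when genes were chosen by the response without or with GSK-J4, which follows from choosing on a term of the difference. It was -0.52 with the response taken against untreated. For repressed genes it was 0.31 with library totals, 0.15 with upper quartiles, and 0.62 or -0.72 with those choices. The list median of lysosomal genes for LPS turned to -0.55 with library totals and -0.0658 with upper quartiles. This follows from the shift of all genes, by -0.68 and -0.19, and the list stayed at percentiles 1.76 and 1.17. With a minimum of 100, H3K27 enzymes for GSK-J4 turned to -0.0519 and hypoxia genes for GSK-J4 with LPS against LPS to -0.16, with fewer members. The cause of the turns with this minimum was not tested. Counted over lists, comparisons and settings together, 1189 other list medians kept their side of the central 95%, although some inside it changed sign. In the same count 10 came inside and 9 went outside. Scaling moves a list and its random lists alike and could hardly change this, unlike a change of minimum. With a minimum of 5, 4 came inside and 6 went outside. Among named genes, also counted over settings, 4652 values kept their side of 2-fold, 75 came under it and 49 went past it. Of those past it 0 changed sign.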

Other observations

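For the LPS responses with minus without GSK-J4, NRF2 antioxidant genes had a median difference of 0.77 (percentile 100), and 7 of 17 members had a difference of 1 or more. Ribosomal protein genes had a median difference of -0.94 (percentile 0, 7 of 29 at -1 or less) and NF-kB pathway genes -0.74 (percentile 0.02, 5 of 25). Macrophage markers had -0.89 (percentile 0.08), granulocyte markers -2.42 (percentile 0) and dendritic cell markers -1.46 (percentile 0, 7 of 11 at -1 or less). Stromal and endothelial markers had -1.10 (percentile 1.99), which lay inside the central 95% with a minimum of 5. Among the widest gains of LPS-induced genes were the MAPK phosphatase Dusp4, with responses of 1.56 without and 3.96 with GSK-J4, and the signalling inhibitor Spry1, with a difference of 2.18. The list of metallothioneins, zinc and iron handling had a median difference of 0.41 (percentile 99.7), with 3 of 14 at 1 or more and 2 at -1 or less. Between the LPS libraries the transferrin receptor Tfrc was higher with GSK-J4 at 2.04, the ferritin light chain Ftl1 at 1.13 and the cystine transporter Slc7a11 at 1.37. None of these differences was tested, since each group has 1 library.

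In the LPS libraries, labelled 1 hour, the median of secondary LPS genes lay above that of immediate-early genes by 3.64 on the log2 scale without and 2.33 with GSK-J4. At least 4-fold lower with LPS were 448 genes without and 582 with GSK-J4. If transcription had stopped when LPS was given, each would need a half-life of 30 minutes or less. These values did not settle whether the exposure matched the label, and the half-life figure holds only if it did. No explanation of them was tested.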
